A study of Homo sapiens with 6 samples.

How the data were processed

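Small RNA sequencing was done on RNA from exosomes, small membrane vesicles that cells release, collected from the culture medium of HaCaT cells. HaCaT is an established line of human skin keratinocytes. Per the labels, RNA was extracted with Trizol and libraries were made with a NEBNext small RNA kit, and the exosomes were isolated by ultracentrifugation. The 6 libraries comprise 3 of exosomes from untreated cells and 3 of exosomes from cells given 0.4 mM hydrogen peroxide (H2O2), and the labels call the replicates biological. The labels give the H2O2 libraries times of 24, 25 and 26 h for replicates 1, 2 and 3, while the series text gives 24 h for the group. Time and replicate number can therefore not be separated, and the 3 libraries were treated as 1 group.

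Per the submitters' processing notes, the upstream tools included bcl2fastq, FastQC, cutadapt and Bowtie 1.1.1. The genome build, the miRNA catalogue release, the counting rules and the software behind the fold changes are not given in the sources used here. The 4 tables used here hold known miRNAs listed as higher, known miRNAs listed as lower, and the same for miRNAs that the authors predicted from the reads. Per the file headers, the authors deposited raw read counts for each library. They also deposited a normalized value, which the counts show to be the count per 1000000 reads (CPM) of a library total chosen by the authors. The totals were recovered by dividing count by CPM, were the same in all 4 tables, and were 3163552, 2644362 and 5405525 reads for untreated replicates 1 to 3. For H2O2 replicates 1 to 3 they were 3079094, 2449856 and 4131478 reads. Which reads those totals count is not given in the sources used here. The authors deposited a log2 fold change, the matching fold (a ratio) and a p-value with no adjustment. In the authors' deposited table the highest p was 0.049 and the smallest absolute log2 fold change was 1.03. The tables used here therefore hold rows selected for a difference between the groups, and the number of miRNAs behind that selection is unknown.

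This selection affects every count of calls. The spread between libraries was estimated from selected rows, and the adjustment for multiple tests covers those rows alone, so the adjusted p-values are too small by an unknown amount and the counts describe the selection. To show the size of this, the p-values were also adjusted as if 2000 miRNAs had been tested.

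The counts were tested with edgeR 4.0.16 in R 4.3.3, with estimateDisp, glmQLFit and glmQLFTest, a two-sided quasi-likelihood test. The recovered library totals were used with no composition factor, since selected rows cannot give one. Rows with at least 5 counts in at least 3 libraries were tested, known and predicted together, with Benjamini-Hochberg adjustment and a threshold of 0.05. Positive log2 fold changes mean higher in H2O2 exosomes. Standard errors (SE) are the fold change divided by the root of the F statistic. Mean levels are CPM with the SD over 3 libraries.

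The miRNAs named were chosen by a rule fixed before the data were examined. Among known miRNAs it took the 10 largest rises and the 10 largest falls that passed the test, had a mean of at least 10 CPM in the higher group and had groups that did not overlap. It also took the 5 most abundant known miRNAs, 7 miRNAs to be named if listed, of which only miR-31-3p was listed, and the 4 most abundant members of each list. Among predicted miRNAs it took the 3 largest rises and the 3 largest falls under the same conditions. The 13 miRNA lists, fixed at the same time, are the let-7 family, the miR-17-92 and paralog clusters, the miR-200 family, keratinocyte and epidermis, redox-responsive, p53-responsive, inflammation and NF-kB, melanocyte and pigmentation, blood cell and serum, muscle, neural and stromal, the DLK1-DIO3 cluster, the chromosome 19 cluster, and entries overlapping other abundant RNA classes. Members were matched by hairpin name, so either strand of a hairpin counted. Some members are therefore not the strand that a family or cell type is known for. A list with at least 3 tested rows was tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, all in limma 3.58.1 and edgeR. Camera compares a list with the other listed rows, while fry asks whether its members move one way. Fry takes no account of the selection of its members on these same libraries, so its p-values are too small by an unknown amount.

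Alternatives were median-of-ratios and TMM scaling, no filter, at least 20 counts, a replicate block, DESeq2 1.42.0, limma on log2(CPM + pseudocount) with pseudocounts of 1, 0.1 and 5, a fold of at least 2, and each library left out in turn. Those chosen after seeing the data were 1 row per set of identical counts, library totals without miR-1246 reads, a factor matching the authors' fold changes, and the adjustment to 2000 miRNAs. Taking miR-1246 reads out of the totals also took out the distinct predicted entries matched to miR-1246. Together these made up 34.68% of the total in H2O2 replicate 3, and whether they share reads is not known. The tests were checked on 276 simulated rows drawn from the tested rows, with 200 rows changed and 3 libraries per group. In that simulation of the H2O2 and untreated libraries, edgeR called 24% of 50 rows changed 2-fold, 72% of 50 changed 4-fold, 98% of 50 changed 8-fold and 100% of 50 changed 16-fold, and 0 of 76 unchanged rows. The simulated spread came from the selected rows, and the shares hold for rows of that spread only. It followed the fitted trend, with no spread particular to a row and no outlying library. The simulated rows were also not selected for a difference between the groups. The 0 of 76 is therefore not a rate of false calls for the real rows.

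Hairpin positions are those of the hairpin gene of the same name in GENCODE release 29 (GRCh38), since the files give no coordinates. Of 161 known rows, 159 had such a gene. A floor of 3 counts corresponds to between 0.555 and 1.225 CPM depending on the library. Intervals for a share of 1 library are exact Clopper-Pearson 95% intervals. Reads carry no molecular identifiers in the files, so floors and intervals cover counting error only. Of the 276 rows, 43 share their 6 counts with another row, and there are 250 distinct sets of counts, so related or repeated entries are not independent.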

Results

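The series asked how the miRNA content of exosomes from HaCaT keratinocytes differs after the cells are given H2O2, an oxidant. Exosomes of 3 H2O2-treated and 3 untreated cultures were compared, with library totals of 2449856 to 5405525 reads. The tables used here list 161 known and 115 predicted miRNAs, all selected by the authors as different between the groups. The counts below therefore describe these selected rows and not the whole miRNA population.

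Exosomes of H2O2-treated cells carried more miR-1290 and miR-31-3p and less let-7a-3p, miR-34c-5p and miR-486-5p than exosomes of untreated cells, and these 5 kept their calls whichever library was left out. So did others, among them miR-5701 and miR-10400-5p, which were near the floor in untreated libraries. Rows were selected for a difference on these same libraries, so keeping a call is not independent support. All 5 lost their calls when adjusted as if 2000 miRNAs had been tested. The strand miR-31-3p, from a hairpin known for its role in keratinocyte growth, rose from 91.9 ± 86.2 to 574 ± 21.0 CPM (SD, n = 3 each). Its log2 fold change was 2.64 ± 0.63 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0119), and 3.76 ± 0.39 without untreated replicate 3. The most abundant miRNA that fell, miR-148a-3p, went from 72677 ± 19965 to 21868 ± 7534 CPM (SD, n = 3 each), a log2 fold change of -1.73 ± 0.53 (edgeR adjusted p = 0.0253), but it no longer passed without H2O2 replicate 1, H2O2 replicate 2, untreated replicate 2 or untreated replicate 3, or with miR-1246 reads taken out of the totals. Of the 127 known miRNAs with enough counts, 39 rose and 61 fell, and 27 did not pass the test. The balance depended on the scaling, as 24 rose and 66 fell with median-of-ratios scaling, and 46 rose and 31 fell with miR-1246 reads taken out of the totals. All tested rows went in the direction in which the authors listed them, which was largely fixed in advance, since the rows were selected on the same counts. In 135 of the 161 known rows the 2 groups did not overlap, where chance gives 10% for 3 against 3, but the rows were selected for a difference. Adjusted as if 2000 miRNAs had been tested, 2 known miRNAs (miR-5701 and miR-10400-5p) stayed below the threshold. Leaving out a single library left between 24 known calls, without H2O2 replicate 1, and 83, without untreated replicate 3. It left 46 without untreated replicate 1, 43 without untreated replicate 2, 64 without H2O2 replicate 2 and 61 without H2O2 replicate 3.

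**Figure D1:**
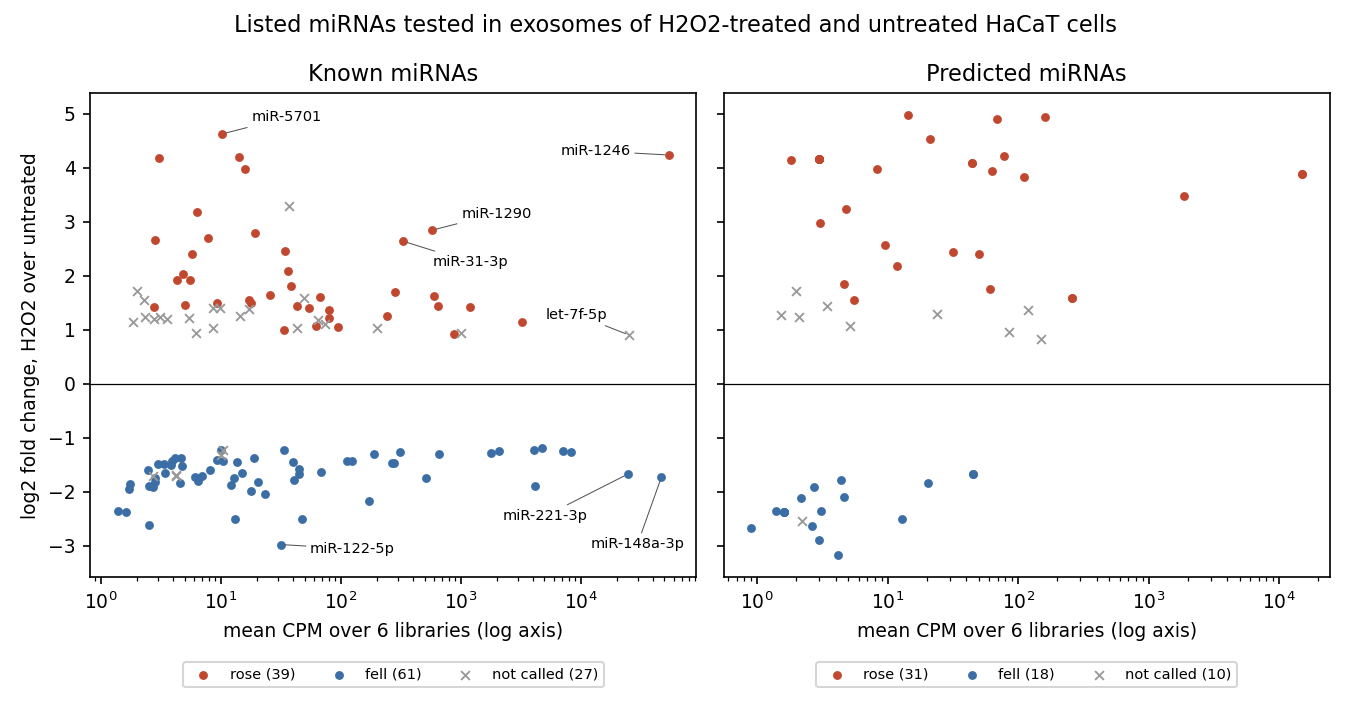
Log2 fold change of each tested miRNA, H2O2 over untreated, against its mean CPM over 6 libraries on a log axis, for known miRNAs (left) and predicted miRNAs (right). Red points rose, blue points fell and grey crosses did not pass the edgeR test; 39 known miRNAs rose and 61 fell with library totals as scaling, and the rows were selected by the authors for a difference.

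Among the largest rises, several started near the detection floor. miR-5701 rose from 0.727 ± 0.398 to 19.8 ± 6.48 CPM (log2 fold change 4.63 ± 0.63, edgeR adjusted p = 0.0023), and 3 hairpin genes carry its name, so its reads cannot be placed at 1 locus. miR-10400-5p rose by 4.21 ± 0.68 and miR-130a-5p by 3.97 ± 0.95 on the log2 scale. miR-4286, miR-582-5p and miR-362-5p rose by 3.17 ± 0.68, 2.79 ± 0.51 and 2.46 ± 0.49. miR-1290 was the most abundant of these, at 141 ± 38.6 CPM in untreated and 1014 ± 505 CPM in H2O2 exosomes (SD, n = 3 each), with a log2 fold change of 2.84 ± 0.49 (edgeR adjusted p = 0.00529). Its hairpin lies on chromosome 1 at 18897071 to 18897148, in an intron of ALDH4A1. miR-1248 and miR-1291 rose by 2.70 ± 0.66 and 2.10 ± 0.50, and their hairpins overlap the snoRNA genes SNORA81 and SNORA2C. Some of these sizes depended on 1 library. Without untreated replicate 3 miR-130a-5p rose by 6.32 and miR-4286 by 3.96, and without H2O2 replicate 2 miR-10400-5p rose by 3.51 and miR-1248 by 2.08. The sizes near the floor also depended on the pseudocount. With limma and a pseudocount of 5, the log2 fold change was 2.09 for miR-5701, 2.15 for miR-10400-5p, 2.396 for miR-130a-5p, 1.36 for miR-4286, 1.97 for miR-582-5p and 1.28 for miR-1248, and all 6 still passed.

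The largest falls included miR-122-5p, a liver miRNA, which went from 56.3 ± 53.4 to 7.12 ± 2.63 CPM (SD, n = 3 each; log2 fold change -2.98 ± 0.73, edgeR adjusted p = 0.0128). Its hairpin lies on chromosome 18 at 58451074 to 58451158, in an exon of MIR122HG. miR-27a-5p, miR-548e-3p and let-7a-3p also fell, with log2 fold changes of -2.51 ± 0.59, -2.50 ± 0.64 and -2.18 ± 0.46. miR-34c-5p, a member of the p53-regulated miR-34 family, fell from 63.0 ± 12.9 to 18.2 ± 4.59 CPM (SD, n = 3 each; log2 fold change -1.79 ± 0.42, edgeR adjusted p = 0.0119). The red cell miRNAs miR-486-5p and miR-451a fell, with log2 fold changes of -1.997 ± 0.49 and -1.80 ± 0.59. miR-148b-3p, miR-597-3p and miR-6510-3p fell, with log2 fold changes of -1.89 ± 0.53, -1.88 ± 0.54 and -1.83 ± 0.57. Without untreated replicate 2 the value was -1.86 ± 0.55 for miR-122-5p and -1.68 for miR-27a-5p, and without untreated replicate 3 it was -1.24 for miR-148b-3p. Without H2O2 replicate 2 it was -3.24 for miR-548e-3p and -2.47 for miR-451a. With limma and a pseudocount of 5 it was -2.01 for miR-122-5p, -1.61 for miR-548e-3p, -1.21 for miR-597-3p and -0.94 for miR-451a. Without H2O2 replicate 1, miR-122-5p, miR-548e-3p, miR-148b-3p and miR-451a no longer passed. miR-451a and miR-597-3p were lost without untreated replicate 2, miR-451a and miR-6510-3p without H2O2 replicate 3, and miR-6510-3p without untreated replicate 1.

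Among the most abundant miRNAs, miR-221-3p fell from 37807 ± 6868 to 11840 ± 3456 CPM (SD, n = 3 each; log2 fold change -1.67 ± 0.48, edgeR adjusted p = 0.0202). Its hairpin lies on chromosome X at 45746157 to 45746266. miR-183-5p fell from 11717 ± 1696 to 4884 ± 343 CPM (SD, n = 3 each; log2 fold change -1.26 ± 0.40, edgeR adjusted p = 0.0257). let-7f-5p did not pass the test, with 17843 ± 7238 CPM in untreated and 33276 ± 9782 CPM in H2O2 exosomes (SD, n = 3 each; log2 fold change 0.90 ± 0.52, edgeR adjusted p = 0.12). The fall of miR-221-3p no longer passed without H2O2 replicate 1 or untreated replicate 2. That of miR-183-5p no longer passed without H2O2 replicate 1, untreated replicate 1 or untreated replicate 2, or with miR-1246 reads taken out of the totals.

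Over all 6 libraries miR-1246 had the highest mean level of the listed known miRNAs, carried by 274467 CPM in H2O2 replicate 3. In untreated exosomes it was at 5481 CPM on average, against 72677 CPM for miR-148a-3p. It made up 0.1295%, 0.3676% and 1.147% of the total in untreated replicates 1, 2 and 3, and 3.324%, 0.2608% and 27.45% in H2O2 replicates 1, 2 and 3. The exact 95% interval of the last was 27.4% to 27.49%. The fitted log2 fold change was 4.24 ± 1.48 (edgeR adjusted p = 0.0293), but the groups overlapped, since H2O2 replicate 2 lay below untreated replicates 2 and 3. The value was 1.71 ± 1.02 without H2O2 replicate 3 (edgeR adjusted p = 0.138) and 5.38 without untreated replicate 3. It did not pass with limma at any of the 3 pseudocounts, or without H2O2 replicate 1, H2O2 replicate 3, untreated replicate 1 or untreated replicate 2. Its hairpin, on chromosome 2 at 176600980 to 176601052, shares a stretch of at least 18 bases with the U2 spliceosomal RNA gene RNU2-1, and reads from that stretch cannot be assigned to 1 of them by sequence.

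**Figure D2:**
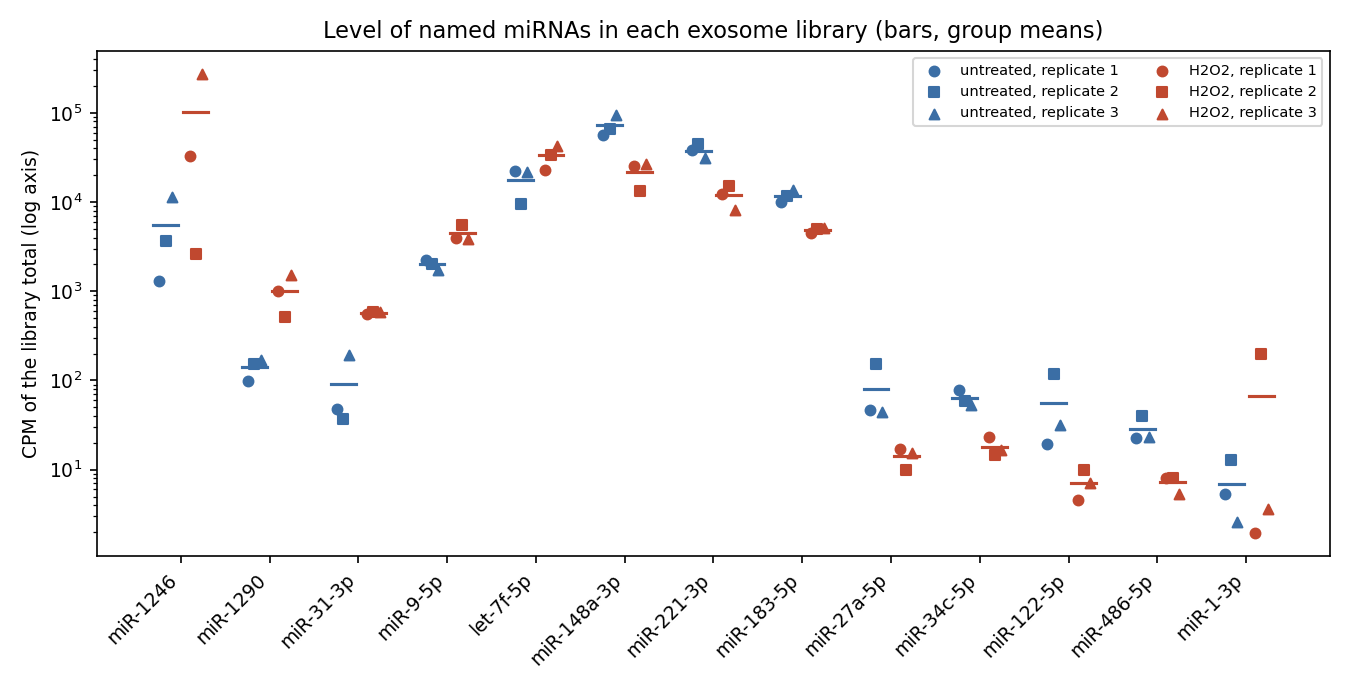
Level of named miRNAs in CPM of the library total (log axis) in each of the 6 libraries, with blue for untreated and red for H2O2 exosomes, symbols for replicates and bars for group means. miR-31-3p lies between 551 and 592 CPM in the H2O2 libraries and between 36.7 and 191 CPM in the untreated ones, while miR-1-3p is high in H2O2 replicate 2 alone.

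The 13 miRNA lists were fixed before the data were examined. Passing when adjusted over a list alone was largely fixed by the selection of rows. Of 127 tested known rows, 109 had an unadjusted edgeR p under 0.05. With camera and Benjamini-Hochberg adjustment over the 9 lists with enough rows, 0 passed at the preset correlation and 0 with an estimated correlation, while 2 had an unadjusted camera p under 0.05 and 2 passed with fry (keratinocyte and epidermis, and entries overlapping other abundant RNA classes). In the blood cell and serum list all 5 tested members fell, namely miR-122-5p, miR-486-5p, miR-451a, miR-142-5p and miR-16-2-3p, and 5 passed adjusted over the list alone. Camera gave p = 0.0139 and adjusted p = 0.125, adjusted p = 0.925 with an estimated correlation, and fry gave adjusted p = 0.0589. Fry passed with median-of-ratios (0.0346) and TMM scaling (0.0438) and with miR-1246 reads taken out of the totals (0.0496), and in none of the 6 runs without a library. Of the 5, 1 passed without H2O2 replicate 1, 2 without untreated replicate 2 or H2O2 replicate 3, 3 without untreated replicate 1 and 4 without H2O2 replicate 2. Of the 5, 4 passed with the replicate block, with no filter, with limma at a pseudocount of 0.1, with the authors' factor and with miR-1246 reads taken out of the totals. In the list of entries overlapping other abundant RNA classes, 6 were listed, all higher, and the 4 tested (miR-1246, miR-1290, miR-4488 and miR-4516) rose, with 4 passing adjusted over the list alone. Camera gave adjusted p = 0.182, adjusted p = 0.925 with an estimated correlation, and fry gave adjusted p = 0.00219, and at most 0.0398 in all 11 settings in which it was run. All 6 were selected as higher on these same libraries, so passing with fry was largely fixed by the selection. Without H2O2 replicate 1 or untreated replicate 1, 2 of the 4 tested members passed. miR-4488 had 1 count in each untreated library, below the floor of 3 counts, and 13, 26 and 10 counts in H2O2 replicates 1 to 3. miR-4516 no longer passed without H2O2 replicate 1, H2O2 replicate 2, untreated replicate 1 or untreated replicate 3. Of the 4, only the miR-1246 hairpin shared 18 bases with a small structural RNA gene in GENCODE release 29. The search covered no nuclear tRNA genes, so it could not find tRNA fragments. Whether it covered the large ribosomal RNAs in full was not checked.

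In the keratinocyte and epidermis list miR-31-3p rose and the other 4 tested members fell, namely miR-183-5p, miR-125b-1-3p (-1.64 ± 0.39), miR-125b-2-3p (-1.44 ± 0.39) and miR-205-3p (-2.05 ± 0.83). All 5 passed adjusted over the list alone. Camera gave adjusted p = 0.605, adjusted p = 0.925 with an estimated correlation, and fry gave adjusted p = 0.0458, which did not pass with miR-1246 reads taken out of the totals (0.162), with the authors' factor (0.0566) or in any run without a library but that without untreated replicate 1 (0.0138). The highest of these was 0.202, without H2O2 replicate 1. Of the 4 falls, 1 passed without H2O2 replicate 1, 2 without untreated replicate 1, without untreated replicate 2 or with miR-1246 reads taken out of the totals, and 3 without H2O2 replicate 3 or with the authors' factor. The groups of miR-205-3p overlapped. In the redox-responsive list 4 of 7 rose, namely miR-9-5p (1.15 ± 0.38), miR-23b-3p (1.44 ± 0.59), miR-181a-3p (1.40 ± 0.48) and miR-181a-2-3p (1.37 ± 0.45), and 3 fell, namely miR-27a-5p, miR-34c-5p and miR-424-3p. All 7 passed adjusted over the list alone, the median log2 fold change was 1.15 and the mean -0.08, and camera gave adjusted p = 0.921. With median-of-ratios scaling 1 of the 4 that rose passed, and 0 of the 4 without untreated replicate 1, untreated replicate 2, H2O2 replicate 1 or H2O2 replicate 2. The groups of miR-23b-3p overlapped, and it did not pass with the replicate block. Without untreated replicate 3 miR-23b-3p was at 2.07. Of the 3 falls, 2 passed without H2O2 replicate 1 or H2O2 replicate 3.

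In the p53-responsive list 2 of 4 rose (miR-1246 and miR-103a-2-5p) and 2 fell (miR-34c-5p and miR-16-2-3p), 4 passed adjusted over the list alone, and camera gave adjusted p = 0.921. Without untreated replicate 3 miR-103a-2-5p was at 2.98, and without H2O2 replicate 2 miR-16-2-3p was at -2.47. Of the 6 runs without a library, miR-103a-2-5p passed only without untreated replicate 3, and miR-16-2-3p only without untreated replicate 3 or H2O2 replicate 2. Without untreated replicate 1, untreated replicate 2, H2O2 replicate 1 or H2O2 replicate 3, 0 of the list rose and 1 fell. Camera pointed down although the median log2 fold change was 0.09 and the mean 0.65. In the inflammation and NF-kB list miR-31-3p and miR-9-5p rose, miR-221-3p and miR-221-5p fell, and miR-212-3p did not pass. Of the rises 1 passed in every run without a library but that without H2O2 replicate 3, and of the falls 1 passed without untreated replicate 2 and 0 without H2O2 replicate 1. Over that list alone 4 passed, and camera gave adjusted p = 0.921. In the let-7 family let-7i-3p rose (1.55 ± 0.53), let-7a-3p and let-7c-3p fell, and let-7f-5p and let-7g-3p did not pass. Adjusted over the list alone, 3 passed. All but let-7f-5p are 3p strands of let-7 hairpins. let-7i-3p no longer passed with median-of-ratios scaling or without H2O2 replicate 1, H2O2 replicate 2, untreated replicate 1 or untreated replicate 3. Of the 2 falls 1 passed without untreated replicate 2 or any H2O2 replicate. The list median log2 fold change was 0.90 and the mean -0.08, and camera gave adjusted p = 0.921.

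In the miR-17-92 and paralog clusters 0 of 4 passed, with log2 fold changes of 0.94 ± 0.49 for miR-19b-3p, 1.38 ± 0.60 for miR-17-3p, 1.03 ± 0.49 for miR-20a-3p and 1.20 ± 0.58 for miR-19b-1-5p. None passed adjusted over the list alone with edgeR (0), while miR-17-3p had an unadjusted p of 0.0451, and camera gave adjusted p = 0.621. miR-17-3p passed in 6 other settings, namely DESeq2, the replicate block, no filter, miR-1246 reads taken out of the totals, the authors' factor and without H2O2 replicate 3, and miR-20a-3p in 2, with at least 20 counts and with the authors' factor. In the melanocyte list miR-148a-3p fell and miR-330-5p rose (1.07 ± 0.43), and 2 passed adjusted over the list alone. miR-330-5p passed neither with median-of-ratios nor TMM scaling, and of the runs without a library only in that without untreated replicate 3. In the muscle, neural and stromal list miR-9-5p rose and miR-219a-1-3p fell (-1.45 ± 0.46), and 2 passed adjusted over the list alone, while miR-1-3p, a muscle miRNA, did not pass at 3.30 ± 1.504 and camera gave adjusted p = 0.921. Without untreated replicate 1, H2O2 replicate 1 or H2O2 replicate 2, 0 of the 3 tested members passed, and miR-219a-1-3p did not pass with miR-1246 reads taken out of the totals. miR-1-3p was at 197 CPM in H2O2 replicate 2, against 1.95 and 3.63 CPM in the other H2O2 libraries and 5.37, 12.9 and 2.59 CPM in untreated ones, and its log2 fold change was -1.24 without that library. It passed with no filter, with miR-1246 reads taken out of the totals and without H2O2 replicate 3 (3.86). No member of the miR-200 family was listed (0), and the DLK1-DIO3 and chromosome 19 clusters had 1 listed member each, miR-329-3p and miR-1283, both below the filter.

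**Figure D3:**
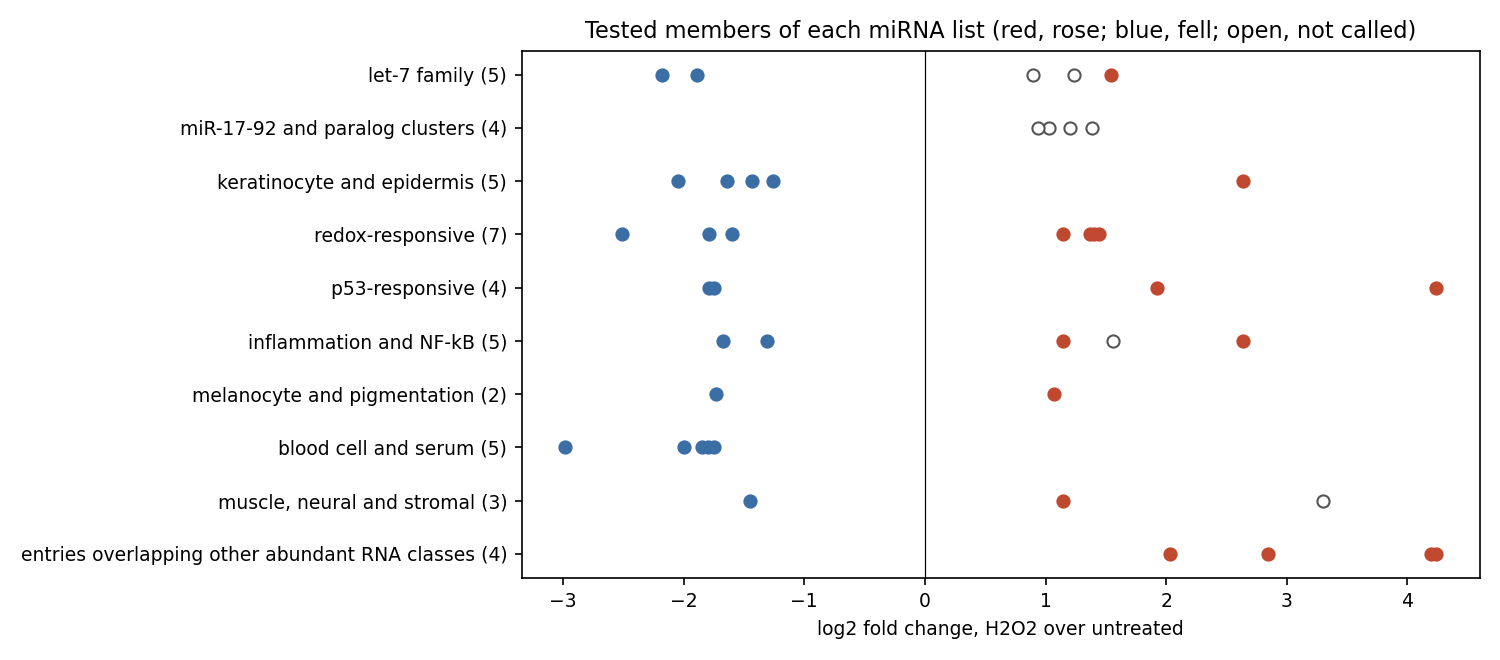
Log2 fold change, H2O2 over untreated, of the tested members of each miRNA list, with the number of tested members in brackets. Red points rose, blue points fell and open points did not pass the edgeR test; all 5 blood cell and serum members lie below 0 and all 4 tested members of the list of entries overlapping other abundant RNA classes lie above 0.

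For the predicted miRNAs, which the authors named by chromosome and number, 59 had enough counts, of which 31 rose and 18 fell. Some of these rows repeat the counts of another row. With 1 row per set of identical counts, 43 predicted rows were tested, of which 24 rose and 11 fell. Under the naming rule, with at least 10 CPM in the higher group and no overlap of the groups, the largest rises were 17_20708-5p (4.97 ± 0.82), 14_18301-5p (4.95 ± 0.60) and 3_5151-5p (4.90 ± 0.67), all with edgeR adjusted p below the threshold. 14_18301-5p went from 10.1 ± 5.16 to 310.0 ± 137 CPM (SD, n = 3 each). Under the same rule the largest falls were 10_13355-3p, 17_21786-3p and 10_13692-3p, at -2.51 ± 0.65, -1.83 ± 0.57 and -1.67 ± 0.43. The value was 6.08 for 17_20708-5p without untreated replicate 1, 4.07 for 3_5151-5p without H2O2 replicate 1 and -3.30 for 10_13355-3p without H2O2 replicate 2. 10_13355-3p no longer passed without H2O2 replicate 1, and 17_21786-3p without H2O2 replicate 3 or untreated replicate 1. With limma and a pseudocount of 5, the value was 2.37 for 17_20708-5p, 3.67 for 3_5151-5p and -1.61 for 10_13355-3p. The counts of 10_13355-3p and 17_21786-3p nearly repeat those of known miRNAs. 10_13355-3p had 61, 81 and 84 untreated counts where miR-548e-3p had 63, 81 and 86. 17_21786-3p had 128, 71 and 157 where miR-6510-3p had 127, 71 and 157. The third, 10_13692-3p, shares its 6 counts with another predicted row. Its log2 fold change was -1.6707 where that of the known miR-3158-3p was -1.6720. Without H2O2 replicate 3 these were -1.8401 ± 0.5192 and -1.8414 ± 0.5194. It may therefore also not be separate from a known miRNA. Adjusted as if 2000 miRNAs had been tested, 5 predicted miRNAs stayed below the threshold, and without the filter 91 of 115 passed, while with at least 20 counts 25 passed. Leaving out 1 library left 25 without H2O2 replicate 1, 30 without untreated replicate 1 and 31 without untreated replicate 2.

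In the authors' deposited table miR-31-3p had a log2 fold change of 2.80 and miR-148a-3p of -1.54. For rows with at least 20 counts in every library, the values of the authors' deposited table lay above the library-total values by a median of 0.17 for known and 0.33 for predicted miRNAs on the log2 scale. For 8 pairs of rows with the same counts in both, the authors' deposited table gave the known entry a lower value in 8, by a median difference of -0.12.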

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

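The main counts were 100 known and 49 predicted miRNAs. With 1 row per set of identical counts, chosen after seeing the data, they were 100 known and 35 predicted. No tested row changed sign under another scaling. This was largely fixed in advance, since the median shifts were small beside the fold changes for which the rows were selected. The balance of rises and falls did move. With median-of-ratios scaling 24 known rose and 66 fell (26.67% rose against 39%; median shift -0.28 on the log2 scale). With miR-1246 reads taken out of the totals, chosen after seeing the data, 46 rose and 31 fell (59.74% rose; shift 0.23), and with the authors' factor 45 rose and 48 fell (shift 0.16). The predicted count was 91 without a filter and 25 with at least 20 counts. Adjusted as if 2000 miRNAs had been tested, also chosen after seeing the data, it was 2 known and 5 predicted, as the larger number of tests alone implies. Leaving out a library gave 24 to 83 known and 25 to 47 predicted calls; fewer samples lower the calls by construction, and no other cause was tested. DESeq2 gave 105 and 50, and limma 101 to 104 and 47 to 49. Whether the replicate numbers pair the samples stays open, as the rows were selected for a difference between the groups. Same-numbered libraries correlated at 0.20, 0.08 and 0.23 in their deviations from the group means. Differently numbered ones correlated at -0.25 to -0.04, except H2O2 replicate 2 with untreated replicate 1 (0.12). Deviations from a group mean cancel within the group, so some negative values are forced once the same-numbered ones are positive. The negative values are therefore not separate evidence of pairing. With the replicate block the counts were 100 known, 92 of them shared, and 51 predicted. Of the libraries, H2O2 replicate 2 correlated more with untreated replicate 1 (0.12) than with its own number. Of 995 values of named miRNAs, 862 kept their direction and side of the threshold, 121 lost and 11 gained the call, and 1 reversed. That was miR-1-3p, which ranged from -1.24 without H2O2 replicate 2 to 4.09 without untreated replicate 2. With camera the lists gave 0 calls under every alternative run. The rows that camera compared with held predicted entries that nearly repeat members of the list of entries overlapping other abundant RNA classes. Those matched to bta-miR-2327, for example, had the same log2 fold change as miR-4488 without H2O2 replicate 3 (4.57). Such rows can raise the camera p-value of that list. The setting with 1 row per set of identical counts was not run with camera. Fry, run in 11 settings, passed in 11 for entries overlapping other abundant RNA classes, 4 for keratinocyte and epidermis, 3 for blood cell and serum, and 1 each for the miR-17-92 clusters (0.0426) and inflammation (0.0448), both with miR-1246 reads taken out of the totals. Since the members were selected on these same libraries, these passes are not independent support.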

Other observations

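All tests of an explanation in this part were chosen after the results they bear on had been seen. Neighbouring miRNAs were examined first, as biology not described above. Among listed known miRNAs with hairpin genes within 10000 bp of each other, 18 of 25 pairs from different hairpins were listed in the same direction (72%, against 49.7% with permuted directions; one-sided permutation p = 0.0346). The pairs include the miR-362, miR-500 and miR-502 cluster on chromosome X, where miR-362-5p was listed higher and miR-502-3p lower. Without that cluster fewer pairs were left, of which 9 of 12 matched (75%; one-sided permutation p = 0.0781). The pairs of these 12 that did not match were miR-15b-5p and miR-16-2-3p, let-7f-5p and let-7a-3p, and miR-425-5p and miR-191-5p. They lie 157, 390 and 470 bp apart. Of pairs that share a hairpin gene, 6 of 8 matched (75%, against 49.7% with permuted directions; one-sided permutation p = 0.14). miR-502-5p, listed higher, and miR-502-3p, listed lower, share 1 hairpin. It remains a hypothesis that shared transcription may contribute, and similar mature sequences within a cluster can share reads.

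The 4 tested members of the list of entries overlapping other abundant RNA classes, miR-1246, miR-1290, miR-4488 and miR-4516, were all called as risen. The groups of miR-1246 overlapped, and miR-4488 was below the floor in untreated libraries. Fragments of structural RNAs counted as miRNAs remain open, since hairpins that overlap or share 18 bases with a small structural RNA gene made up 6 of 78 known miRNAs listed higher and 4 of 81 listed lower (Fisher's exact test, two-sided p = 0.529), while hairpins that overlap a snoRNA or scaRNA gene, a class picked after seeing the data that holds none of these 4, made up 5 of 78 and 0 of 81 (two-sided p = 0.0266). The hairpin search covered no nuclear tRNA genes, so it cannot decide on fragments of those. Without H2O2 replicate 3, miR-1290, miR-4488 and miR-4516 were still called, 3 of 3. For miR-1290, which was highest in that library, this argues against a cause in it alone (log2 fold change 2.43 without it). miR-4488 and miR-4516 had their lowest H2O2 level in that library, at 2.42 and 3.39 CPM. Leaving out H2O2 replicate 3 could therefore not test this for them. For miR-1246 that library is a candidate explanation, as without it the log2 fold change was 1.71 and did not pass. An effect of H2O2 on the cells stays open and was not tested separately.

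The 5 blood cell and serum miRNAs all fell. Rows selected for a difference do not decide whether the H2O2 preparations held less serum or blood cell RNA. All 5 were read in every untreated library, the most abundant being miR-16-2-3p at 796 CPM, and 1 of the 5 is also on the p53-responsive list. miR-16-2-3p is a 3p strand that was matched by its hairpin name. The labels do not say what serum the medium held.

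Some muscle and neural miRNAs were high in H2O2 replicate 2. Besides miR-1-3p, miR-133a-3p had 34 counts there against 0 and 1 in the other H2O2 libraries, and miR-124-3p had 14 against 0 and 1. The authors listed these rows as higher, which counts like these can bring about, so the listing itself favours members that are high in 1 H2O2 library. These rows do not decide where their reads come from. The library is labelled 25 h where the others are labelled 24 and 26 h.

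Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many known calls and 1 as many predicted calls as the real one, which is the real one itself. The real split gave 100 known calls against at most 2 in another split, and 49 predicted calls against at most 4, on rows that were selected on the real split. For the lists the real split gave 0 and the highest other 2, so 10 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached.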
